A study of Mus musculus with 2 samples.

How the data were processed

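H3K9ac ChIP-seq was performed on hindbrain tissue of mouse embryos at embryonic day 16.5, per the labels. The labels name the B6NCrl strain, mixed-sex pools of embryos and 2 biological replicates of a single group. Replicate 2 was made from 37 mice, and no number of mice is used here for replicate 1. Each replicate is a separate biosample of pooled tissue in the labels. The p-values below therefore describe peaks and genes within these lists, and none of them measures the spread between embryos.

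4 deposited peak lists on the mm10 assembly were analysed. Per the deposited notes on each file, 1 list was called on each replicate alone, 1 on both replicates together (the pooled list), and 1 was made from the other 3 lists (the replicated list). The rule behind the replicated list, the peak caller, the aligner and their versions are not given in the sources used here. The notes record that the replicate 1 list was derived with more input files than the replicate 2 list, and those inputs are not named there. Each peak carries a fold enrichment, a linear ratio of ChIP signal over background that the authors' peak caller assigned. The deposited lists also give a −log10 p and a −log10 q for each peak, and the distance of its summit from its start. The lowest −log10 p lay between 2.01 and 2.05 in every list, so the authors reported peaks at p of 0.01 or less. Fold enrichments and −log10 p values were used only to describe, rank or filter peaks of their own list, apart from the rank correlation over matched peaks. Values from different lists printed side by side are therefore not on 1 scale.

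Read numbers and sequencing depth are not part of these lists, so depth is unknown and no interval that needs it is given. The lists held 58578 peaks in replicate 1, 40583 in replicate 2, 50764 in the pooled list and 39443 in the replicated list. Between 8 and 11 peaks per list lay on unplaced or unlocalised scaffolds and were left out of all steps that use chromosomes 1 to 19, X and Y. No column of per-sample values was left unused.

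Gene positions came from the GENCODE M21 comprehensive annotation and sequence from the RefSeq GRCm38 assembly, which has the same coordinates as mm10 (chromosome 1 was 195471971 bp long). The annotation held 55413 genes, 141730 transcripts and 21938 protein-coding genes on these chromosomes. A gene had a TSS peak when a peak came within 1 kb of the transcription start site (TSS) of any of its transcripts. Peaks up to 1 kb apart were joined into domains, and the width of a gene's TSS domain was that of the widest domain holding a TSS peak. A peak was TSS-distal when its summit lay more than 2.5 kb from every annotated TSS, and it was assigned to the protein-coding gene with the nearest TSS within 100 kb. The observed over expected CpG ratio was taken within 500 bp of the gene's 5′ end, in bins under 0.4, from 0.4 to 0.6, and 0.6 or more.

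Peaks of the replicates were called shared at an overlap of at least 1 bp. Overlap and location were compared with 1000 random placements of the peaks within their own chromosomes outside assembly gaps of 1000 bp or more, with a one-sided p that can be no smaller than 0.001. Shares of genes were compared with Fisher's exact test, two-sided. Enrichment, domain width and numbers of distal peaks of a gene list were compared with 100000 random lists of the same size, in a two-sided permutation test whose smallest p is 2e-05. Kept and dropped pooled peaks were compared by permuting ranks 100000 times, with a smallest p of 1e-05. Each family of tests over gene lists was adjusted by the Benjamini-Hochberg method and called at 0.05. Genes that neighbour each other can share a peak, so genes are not independent of each other in these tests.

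The 21 gene lists, with 382 entries that all matched the annotation by symbol, the tests, the settings and the rule for named genes were fixed before the data were examined. By that rule the text names up to 4 members with the highest enrichment and up to 4 members without a TSS peak per list. It also names the 20 genes with the widest TSS domain, the 20 with the highest TSS enrichment, the 10 with most TSS-distal peaks and the 10 TSS-distal peaks with the highest enrichment, all from the replicated list. Some genes stand in more than 1 list.

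Alternatives were a q value of 0.01 or less, the strongest 20000 peaks, an overlap of 50% of the shorter peak, TSS windows of 500 bp and 2 kb, the 5′ end of the gene in place of every TSS, peak midpoints, −log10 p in place of enrichment, joining of no peaks or of peaks within 3 kb, distal limits of 5 kb and 50 kb, a CpG window of 1 kb, CpG-rich promoters only, the pooled list, and the list of either replicate alone, which leaves out the other replicate. Added after seeing the data were TSSs of coding transcripts only, genes with no other gene's TSS within 2 kb, and the 5′ end of the gene in the CpG comparison. Tests of 12 gene families and of the X chromosome against the autosomes were also chosen then. Gene lists were also compared with 10000 random lists matched on 10 equal bins of the CpG ratio, a test planned for microglia genes and extended to all 21 lists after the data were seen. The ratio at the 5′ end was matched, whereas a peak at any TSS of the gene counted. Hox coverage in each replicate's own list was added too.

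The code was tested on simulated data. In a list made by keeping 59.9% of 40572 peaks, 59.9% came out as shared. Of 100 simulated lists of 15 genes set to a low share, Fisher's exact test called 100, and it called 1 of 100 lists left at the background share. The permutation test passed 100 of 100 shifted lists at 0.05, and 4 of 100 unshifted ones. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.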

Results

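Acetylation of lysine 9 of histone H3 (H3K9ac), a chromatin mark found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the hindbrain of mouse embryos at embryonic day 16.5. The hindbrain gives rise to the cerebellum, pons and medulla. The series held 1 group with 2 biological replicates, each a pool of embryos of both sexes, and no second tissue, age or treatment. The design therefore bears on how far the replicates shared their peaks, where the peaks lay, and which genes carried them. Replicate 1 had 58578 peaks over 36.0 Mb and replicate 2 had 40583 peaks over 24.0 Mb, with a median width of 322 bp and 375 bp. The replicated list, which combines both, held 39443 peaks over 32.6 Mb, or 1.23% of the genome outside gaps. The number of reads behind these lists is unknown.

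Promoters were the main site of the mark. Of the 39434 replicated peaks on chromosomes 1 to 19, X and Y, 54.6% had their summit within 1 kb of an annotated TSS, against 6.45% on average over 1000 random placements and at most 6.79% in any of them. The smallest p that the placements can give was reached (0.001, one-sided). A further 4.93% lay in exons outside these windows, 24.3% in introns and 16.1% between genes, where random placement gave 3.44%, 40.4% and 49.8%. The share at a TSS was 43.2% in the replicate 1 list and 60.6% in the replicate 2 list.

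A TSS peak was present at 14350 of 21938 protein-coding genes (65.4%). The share was 66.5% in replicate 1 and 64.3% in replicate 2, a mean of 65.4% ± 1.51 (SD, n = 2). The replicates gave the same state for 97.0% of genes: 14012 genes had a TSS peak in both lists, 567 in replicate 1 only and 98 in replicate 2 only. Promoter sequence separated the genes. A TSS peak was found at 97.6% of the 10078 genes with a CpG ratio of 0.6 or more, 84.2% of the 3075 genes between 0.4 and 0.6, and 21.9% of the 8785 genes under 0.4. The difference between the highest and the lowest bin was 75.6 percentage points, with an odds ratio of 143 (Fisher's exact test, −log10 of its one-sided p 2920). With peaks counted only at the 5′ end of the gene, where the CpG ratio was taken, the lowest bin stood at 13.4% and the odds ratio at 241.

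Of the 21 gene lists, 8 had a TSS peak more often than the other protein-coding genes and 6 less often (Fisher's exact test, Benjamini-Hochberg over 21 lists). Among genes with a CpG ratio of 0.6 or more, where nearly every promoter was marked, 4 lists were called, none with a higher share. Against random lists matched on the CpG ratio, 7 lists differed, 3 with more marked genes and 4 with fewer, and 6 of these were among the 14 (permutation tests, Benjamini-Hochberg over 21 lists; chosen for all lists after the data were seen). The calls of hindbrain, anterior Hox, progenitor, GABAergic, housekeeping, erythroid, liver and heart and skeletal muscle genes ended there, and forebrain genes were called with fewer.

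**Figure D1:**
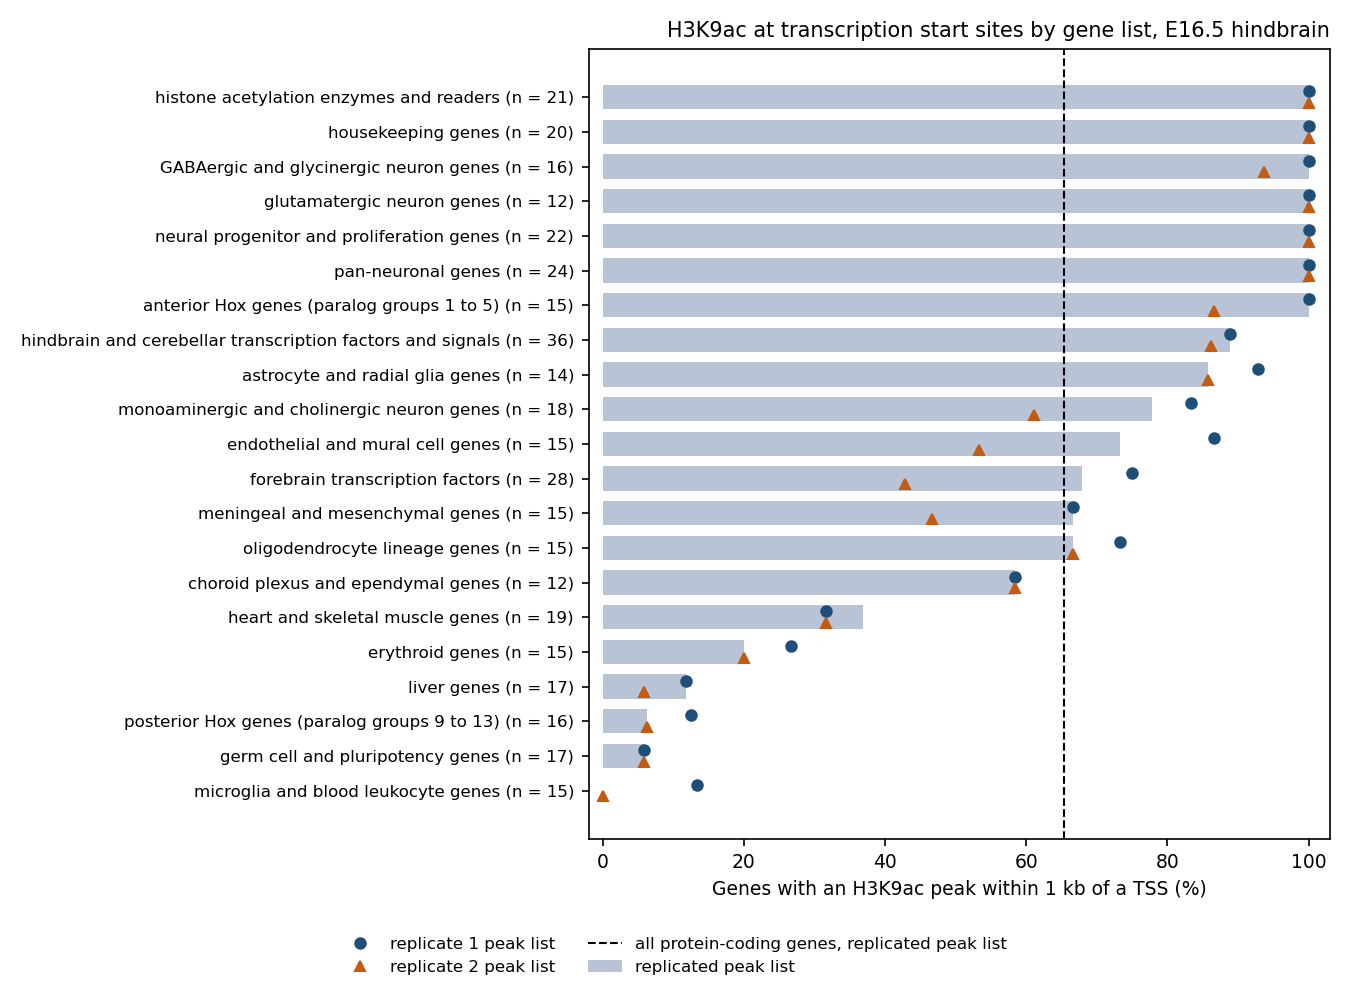
Share of each gene list with an H3K9ac peak within 1 kb of a TSS, in percent on the horizontal axis: bars show the replicated list, circles and triangles the lists of replicates 1 and 2, and the dashed line the 65.4% of all protein-coding genes in the replicated list. Pan-neuronal, progenitor and housekeeping genes reached 100%, and microglia and leukocyte genes stood at 0 in the replicated list.

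All 24 pan-neuronal genes had a TSS peak in both replicates (adjusted p = 0.000199, Fisher's exact test), against 18.4 on average in CpG-matched lists (adjusted permutation p = 0.0014, from the smallest p those lists can give). The highest were Vamp2, a synaptic vesicle protein, with a fold enrichment of 39.5 (42.1 in the replicate 1 list and 25.2 in the replicate 2 list), the neuronal tubulin gene Tubb3 (28.5), the adhesion molecule gene Ncam1 (26.1) and the dendritic microtubule protein gene Map2 (25.1). All 22 progenitor and proliferation genes had one in both replicates (adjusted exact p = 0.000491), led by the RNA-binding protein gene Msi1 (34.4), Mycn (26.1), the Hedgehog receptor gene Ptch1 (25.8) and the Notch target Hes1 (19.4). All 12 glutamatergic genes were marked in both replicates (adjusted exact p = 0.0182), with the transcription factor genes Nhlh2 (16.8) and Pax6 (12.2) and the NMDA receptor genes Grin2b (15.5) and Grin1 (12.8) highest. All 16 GABAergic and glycinergic genes were marked in the replicated list (adjusted exact p = 0.00414), and 15 of them in replicate 2. Slc6a1, which encodes a GABA transporter (21.2), the receptor subunit genes Gabra1 (13.4) and Glra1 (12.3), and Gad2, which encodes a GABA-synthesising enzyme (12.0), led this list. With only the 5′ end of each gene, this list no longer passed (81.3% of genes, adjusted exact p = 0.206). CpG-matched lists held 8.07 marked genes against the 12 glutamatergic ones (adjusted permutation p = 0.00735), 19.2 against the 22 progenitor genes (adjusted permutation p = 0.0882) and 14.0 against the 16 GABAergic and glycinergic genes (adjusted permutation p = 0.220).

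Of 18 monoaminergic and cholinergic genes, 14 had a TSS peak (77.8%, adjusted exact p = 0.432), 15 in replicate 1 and 11 in replicate 2. Gch1, needed for the cofactor of monoamine synthesis, had a fold enrichment of 13.1, Maoa 11.3, the choline transporter gene Slc5a7 9.38 and the vesicular monoamine transporter gene Slc18a2 8.62. No replicated TSS peak was listed at Tph2, Dbh or Th, which encode enzymes of serotonin, noradrenaline and catecholamine synthesis, or at the motor neuron factor gene Isl2. Th had a TSS peak in the replicate 1 list (3.09), and Isl2 had one in the pooled list.

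Astrocyte and radial glia genes had a TSS peak at 12 of 14 (adjusted exact p = 0.223), with Glul (24.6), Slc1a2 (23.0), Nfia (20.9) and Fgfr3 (14.97) highest and no replicated peak at Gfap or S100b. Gfap had a TSS peak in the replicate 1 list (3.25), the replicate 2 list (4.42) and the pooled list. Oligodendrocyte lineage genes had one at 10 of 15 (adjusted exact p = 1). Mbp (22.0), Cnp (14.1), Ugt8a (12.6) and Olig1 (8.10) were marked, and the myelin genes Plp1, Mog, Mag and Mobp were not. The Mbp peak lay at the 5′ end of the annotated gene (chromosome 18, 82474753 to 82476345). Which of its transcripts this peak marks was not examined. Choroid plexus and ependymal genes had one at 7 of 12 (adjusted exact p = 0.890). The cilia regulator genes Rfx3 (30.3) and Foxj1 (13.01), Kl (10.4) and Clic6 (8.74) were marked, and Ttr, Folr1, Aqp1 and Kcnj13 were not. Endothelial and mural genes had one at 11 of 15 (adjusted exact p = 0.740; 13 in replicate 1 and 8 in replicate 2), with Kdr (12.1), Kcnj8 (9.49), Cldn5 (8.27) and Sox18 (6.44) highest and no replicated peak at Pecam1, Cdh5, Tek or Tie1. Pecam1 (2.82) and Cdh5 (4.19) had a TSS peak in the replicate 1 list. Meningeal and mesenchymal genes had one at 10 of 15 (adjusted exact p = 1; 7 in replicate 2). Prrx2 (11.4), Foxc1 (9.14), Twist1 (6.99) and Prrx1 (6.35) were marked, and the matrix genes Col3a1, Lum, Dcn and Postn were not. Dcn had a TSS peak in the pooled list. None of these 5 lists passed the threshold, and they were not tested against each other.

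Genes of blood cells and of other organs were mostly unmarked. Microglia and blood leukocyte genes had a replicated TSS peak at 0 of 15, which allows a share of up to 21.8% (exact 95% limit over genes), with an adjusted p of 2.52e-06 in Fisher's exact test. Aif1, the receptor genes Csf1r and Cx3cr1, and P2ry12 were among those without one. The replicate 1 list had a TSS peak at 2 of the 15, among them Aif1 (3.14). CpG-matched lists held 4.00 marked genes on average (adjusted permutation p = 0.0456). Erythroid genes were marked at 3 of 15 (adjusted exact p = 0.000982): Klf1 (12.6), Gypa (5.26) and Epor (4.47), and not at the globin genes Hbb-bs, Hbb-bt, Hbb-y and Hbb-bh1. CpG-matched lists held 3.15 on average (adjusted permutation p = 1). Liver genes were marked at 2 of 17 (adjusted exact p = 3.93e-05), Apoh (23.1) and Apob (3.43), with 1 of 17 in replicate 2, and not at Alb, Afp, Apoa1 or Apoa2. CpG-matched lists held 5.72 (adjusted permutation p = 0.102). Apoh, like the muscle gene Ckm, has a TSS of another annotated gene within 2 kb of its own. Germ cell and pluripotency genes were marked at 1 of 17, Dazl (12.4), with none at Ddx4, Mael, Sycp3 or Sycp1 (adjusted exact p = 5.00e-06), against 11.2 in CpG-matched lists (adjusted permutation p = 0.0014). Heart and skeletal muscle genes were marked at 7 of 19 (adjusted exact p = 0.0206), with Ckm (9.38), Myod1 (5.95), Myl2 (5.02) and Myh7 (4.43) highest and none at Myog, Myf5, Myf6 or Myh3. This last call ended with the pooled list (8 of 19, adjusted exact p = 0.0678), with a TSS window of 2 kb (adjusted exact p = 0.320) and among genes with no other TSS within 2 kb (adjusted exact p = 0.206), and CpG-matched lists held 7.99 (adjusted permutation p = 0.885). All 20 housekeeping genes (adjusted exact p = 0.000665) and all 21 histone acetylation enzymes and readers (adjusted exact p = 0.000665) were marked in both replicates. CpG-matched lists held 17.8 marked genes against each (adjusted permutation p = 0.105 and 0.0273). Actb (40.0), Ywhaz (37.0), Eef1a1 (36.3) and Rpl13a (36.2) led the former, and Ep300 (36.1), Kat6b (33.6), Brd2 (31.8) and Kat2a (31.3) the latter.

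Hox genes, which set position along the body axis, differed in marking between paralog groups of the 4 clusters. All 15 anterior Hox genes (paralog groups 1 to 5) had a TSS peak, against 1 of 16 posterior Hox genes (groups 9 to 13), a difference of 93.8 percentage points (Fisher's exact test, p = 5.66e-08). In replicate 1 alone the counts were 15 and 2, and in replicate 2 they were 13 and 1. Of the 8 genes in groups 6 to 8, 7 had a replicated TSS peak. Against all other protein-coding genes, the anterior list had an adjusted exact p of 0.00414, which became 0.144 in the replicate 2 list, 0.281 with only the 5′ end of each gene and 0.115 among genes with no other TSS within 2 kb. The posterior list had an adjusted exact p of 9.11e-06. CpG-matched lists held 12.4 marked genes for the anterior list (adjusted permutation p = 0.102) and 15.2 for the posterior list (adjusted permutation p = 0.0014). Hoxa2 (17.6), Hoxb2 (17.3), Hoxa1 (14.6) and Hoxb4 (12.7) had the highest fold enrichments. The marked posterior gene was Hoxb9 (3.74), and Hoxa9, Hoxa10, Hoxa11 and Hoxa13 were without a peak. Replicated peaks covered a median of 38.1% of an anterior gene with 1 kb on either side, 23.8% in groups 6 to 8 and 0 in groups 9 to 13. The annotated span of Hoxa3 ran over Hoxa6, and that of Hoxc5 over Hoxc6, Hoxc8 and Hoxc9. Coverage of these anterior genes therefore took in genes of other groups. The ranges overlapped: coverage ran from 6.04% (Hoxb1) to 88.3% (Hoxa2) in groups 1 to 5 and from 0 to 11.1% (Hoxb9) in groups 9 to 13. In the replicate 2 list the medians were 22.0% in groups 1 to 5 and 7.56% in groups 6 to 8, and in the replicate 1 list they were 48.7% and 28.9%. The widest joined domain of any gene ran over Hoxb2 to Hoxb6 on chromosome 11 from 96299182 to 96355392 (56211 bp). Another, on chromosome 6 from 52157781 to 52181500 (23720 bp), held the TSSs of Hoxa1, Hoxa2 and 5730596B20Rik.

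**Figure D2:**
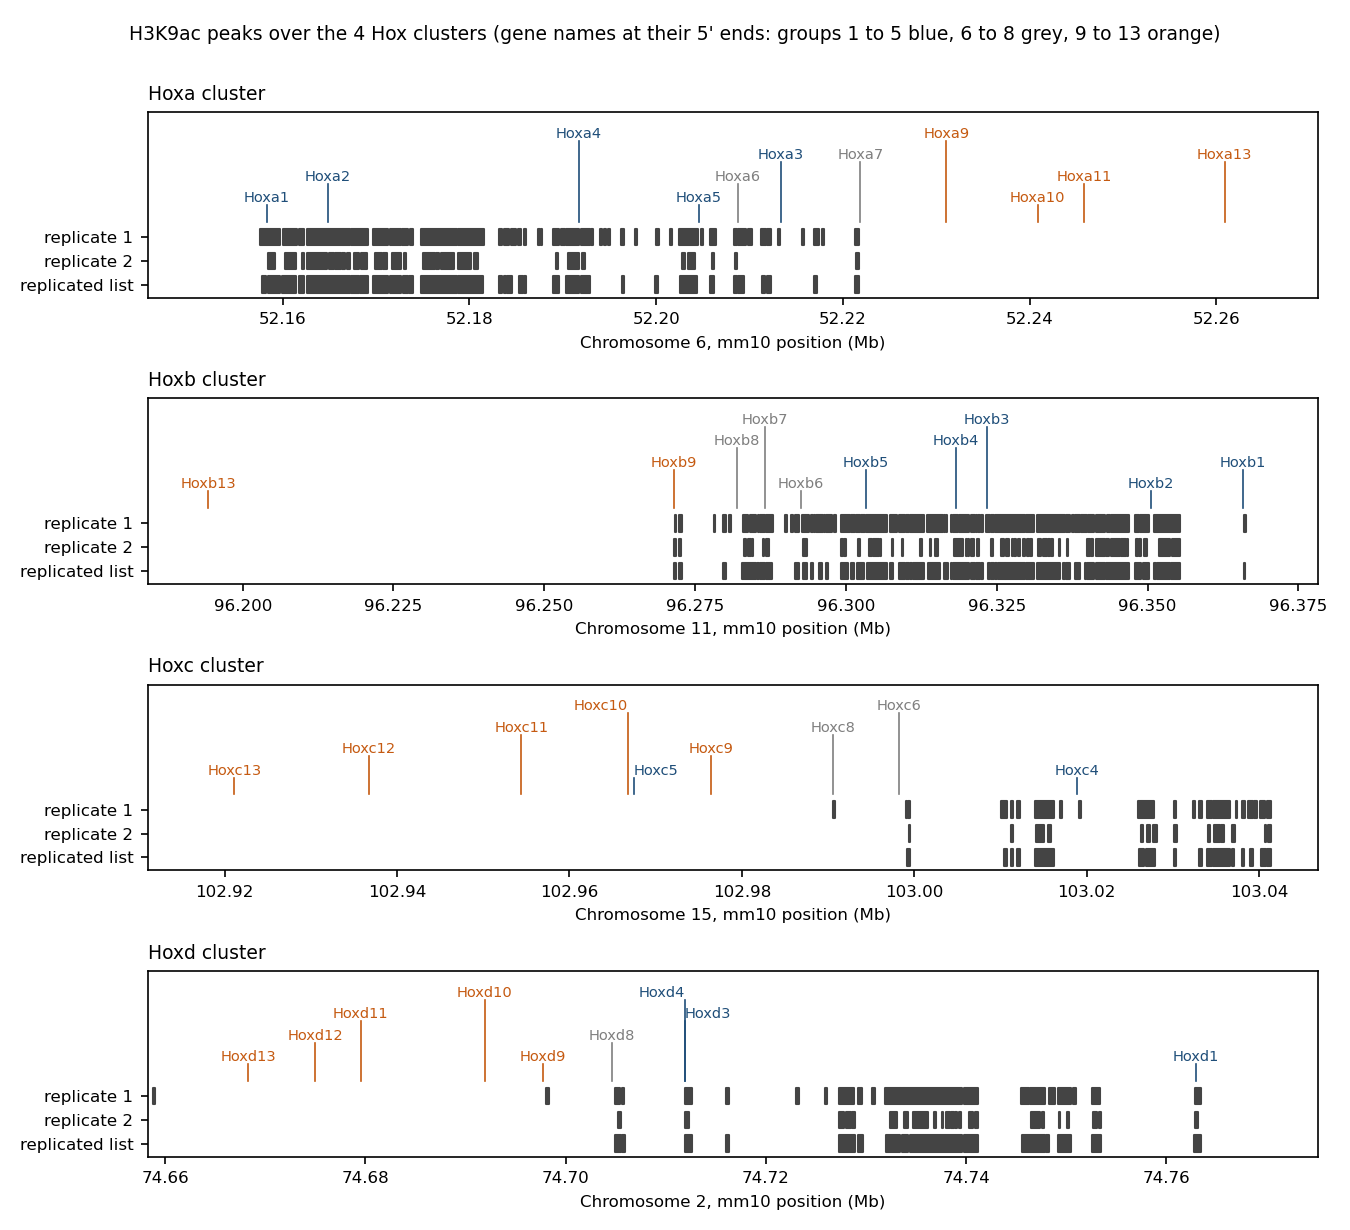
H3K9ac peaks over the Hoxa, Hoxb, Hoxc and Hoxd clusters, with mm10 position in Mb on the horizontal axis. Each peak list has a line of bars. Gene names stand at the 5′ end of the annotated gene, which for Hoxa3, Hoxc5, Hoxd3 and Hoxd4 lies beside genes of other groups. Replicated peaks cover a median of 38.1% of genes in groups 1 to 5 (22.0% in the replicate 2 list) and 0 of those in groups 9 to 13.

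Regional transcription factors of the hindbrain and of the forebrain were both marked in part. Of 36 hindbrain and cerebellar genes, 32 had a TSS peak (88.9%, adjusted exact p = 0.00414 against other genes), with 32 in replicate 1 and 31 in replicate 2. CpG-matched lists held 33.3 marked genes on average, and no difference from these was called (adjusted permutation p = 0.640). Meis1 (30.3; 31.5 in the replicate 1 list and 21.6 in the replicate 2 list), a Hox cofactor gene, Nfib (28.7), Rora (23.9), needed in Purkinje cells, and Irx5 (17.5) were highest, and Phox2b, Evx1, Dbx1 and Prdm13 had none. Evx1 had a TSS peak in the pooled list. Of 28 forebrain genes, 19 had one in the replicated list (67.9%, adjusted exact p = 0.934), with 21 in replicate 1 and 12 in replicate 2. This was fewer than the 23.8 of CpG-matched lists (adjusted permutation p = 0.0202). Bcl11b (21.7), Satb2 (13.5), Lhx2 (8.54) and Lhx8 (5.85) were highest, and Six3, Six6, Rax and Nkx2-1 had none. The difference of 21.03 percentage points had an odds ratio of 3.71 (95% interval 0.885 to 18.8) and did not pass the threshold (Fisher's exact test, p = 0.0594). It passed in the replicate 2 list (43.3 points, p = 0.000396, exact) and not in the replicate 1 list (13.9 points, p = 0.188, exact), and it was 9.24 points among genes with no other TSS within 2 kb (p = 0.678, exact). In the replicate 2 list the forebrain genes also fell below other genes (42.9%, adjusted exact p = 0.0417).

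The lists differed in the height and width of the mark where a TSS peak was present. Over all such genes the median fold enrichment was 17.4 and the median TSS domain 1748 bp. For each gene, height was the highest and width the widest value over all its TSSs. The random lists for height and for width were not matched on CpG ratio or on the number of TSSs. Fold enrichment was higher for housekeeping genes (median 23.6, adjusted p = 0.00139) and for histone acetylation enzymes and readers (25.4, adjusted p = 0.000113), and lower for 14 of the 17 lists tested (permutation tests). Among the lower ones were forebrain transcription factors (4.46), heart and skeletal muscle genes (4.43), GABAergic and glycinergic genes (7.01), hindbrain transcription factors (8.60) and anterior Hox genes (10.1), each with adjusted permutation p of 8.5e-05 or less. The lower enrichment of choroid plexus genes (8.74, adjusted permutation p = 0.0338) no longer passed in either replicate's own list.

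Domains were wider than at other genes for 9 lists and narrower for 5 (permutation tests). Anterior Hox genes had a median domain of 8296 bp, GABAergic and glycinergic genes 4352 bp, pan-neuronal genes 4065 bp, hindbrain transcription factors 3565 bp and progenitor genes 3290 bp (adjusted permutation p of 0.0122 or less). Hoxb2 to Hoxb5 shared 1 domain (56211 bp), and Hoxa1 and Hoxa2 another (23720 bp). The test counted each gene separately, so the anterior Hox p overstates the number of independent values. Glutamatergic genes (3383 bp), astrocyte genes (2870 bp), housekeeping genes (2781 bp) and histone acetylation genes (2379 bp) were also wider. Forebrain transcription factors (533 bp), heart and skeletal muscle genes (440 bp) and monoaminergic and cholinergic genes (834 bp) were narrower (adjusted permutation p of 0.000437 or less), as were endothelial (1333 bp) and meningeal genes (1210 bp). Without joining peaks, 7 lists differed in place of 14, and hindbrain transcription factors (1285 bp, adjusted permutation p = 0.544) and anterior Hox genes (1843 bp, adjusted permutation p = 0.102) no longer passed, nor did GABAergic, progenitor, glutamatergic, astrocyte or housekeeping genes. The pan-neuronal median was then 2572 bp. The anterior Hox median was 3157 bp at a q value of 0.01 or less, and 35150 bp with peaks joined within 3 kb, where the progenitor median was 5490 bp. The calls for endothelial (adjusted permutation p = 0.0767) and meningeal genes (adjusted permutation p = 0.176) ended with that joining. In the replicate 2 list the median fell to 2039 bp for anterior Hox, 2069 bp for GABAergic and glycinergic, 2131 bp for progenitor, 347 bp for forebrain and 622.5 bp for endothelial genes. In the replicate 1 list it was 848 bp for forebrain and 1132 bp for heart and skeletal muscle genes, and these calls held in both lists. Calls for astrocyte and meningeal genes were lost in either replicate's own list, and that for glutamatergic genes in the replicate 2 list.

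**Figure D3:**
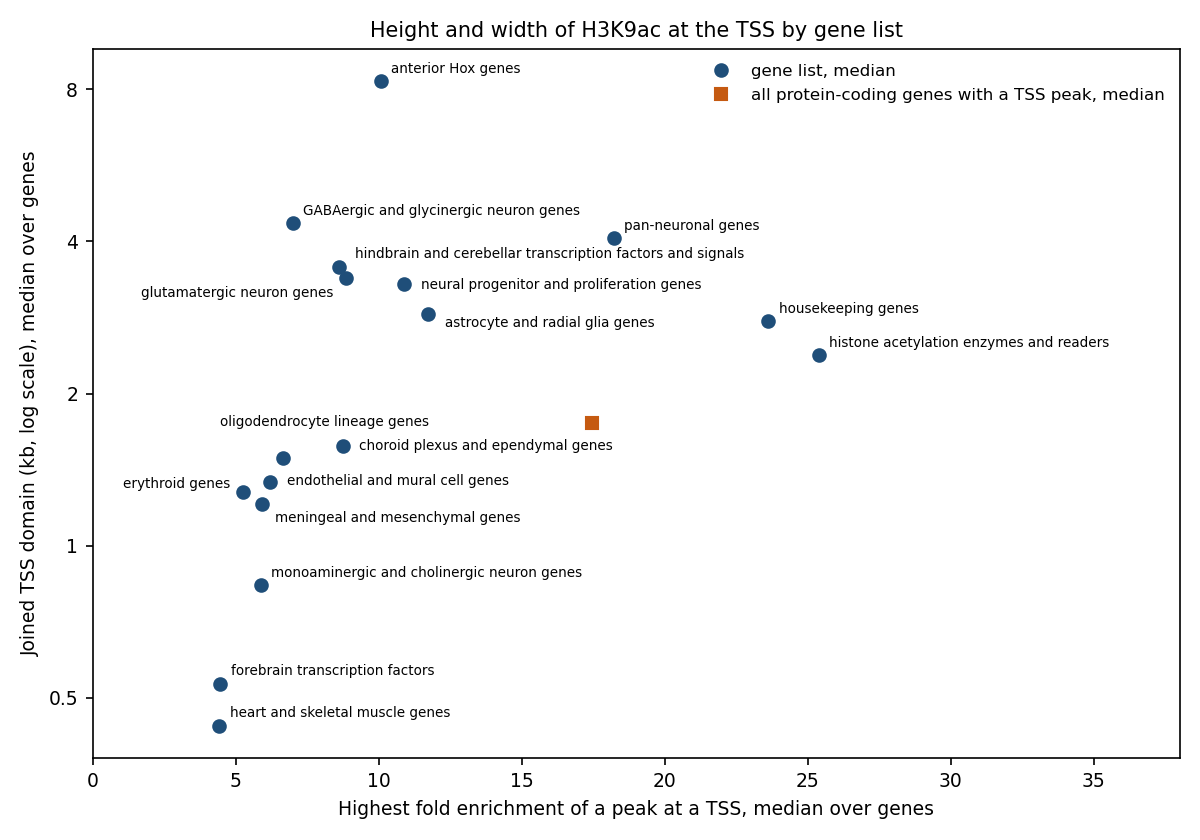
Median fold enrichment of the highest peak at a TSS (horizontal axis) against median width of the joined TSS domain in kb (vertical axis, log scale), for 17 gene lists and, as a square, all protein-coding genes with a TSS peak. Anterior Hox genes lie at 10.1 and 8296 bp, and forebrain transcription factors at 4.46 and 533 bp.

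The widest TSS domains after the Hox clusters belonged to Nfib on chromosome 4 (82494413 to 82513679, 19267 bp), Bahcc1 (17929 bp), Meis2 (17676 bp), Lhx5 (16607 bp) and Ebf3 (16451 bp). Zmynd8 (15787 bp), Meis1 (15414 bp), Setd1b and Rhof (in 1 domain of 15116 bp), Zic2 (14692 bp), Mn1 (14639 bp) and Tnrc18 (14352 bp) completed the 20 widest. Of these, Nfib, Meis2, Lhx5, Meis1 and Zic2 are members of the hindbrain list. The highest fold enrichment at a TSS was at Srsf6, a splicing factor gene, on chromosome 2 from 162930450 to 162932634 (48.1; 50.6 in the replicate 1 list and 33.8 in the replicate 2 list). It was followed by Brsk1 (43.6), Sp3 (43.3), Pabpn1 (43.1), Kmt5b (42.2), Eid2 (41.9) and Basp1 (40.8). Tnpo1, Rbbp6, Dbn1, Sfpq, Rad54l2, Rbm39, Ubr3, Actb, Fam171a2, Marcksl1, Dennd6a, Srsf4 and Vamp2 lay between 40.7 and 39.5. No Hox or forebrain gene was among these 20.

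Of the replicated peaks, 13427 (34.0%) were TSS-distal, and 11651 of these were assigned to 5033 genes. Distal peaks had a median fold enrichment of 3.77 and a median width of 339 bp, against 5.28 and 553 bp over all replicated peaks. The replicate 1 list had 25530 distal peaks (43.6%), of which 21877 were assigned, and the replicate 2 list had 11114 (27.4%), of which 9802 were assigned. Hindbrain transcription factors had 4.14 distal peaks per gene against 0.525 at other genes (adjusted p = 0.000420, permutation test), and 33 of the 36 had at least 1. GABAergic and glycinergic genes had 4.00 (adjusted permutation p = 0.0147), pan-neuronal genes 2.75 (adjusted permutation p = 0.0175) and progenitor genes 2.27 (adjusted permutation p = 0.0239). In the replicate 1 list these 4 lists had 6.56, 6.31, 5.33 and 4.18 distal peaks per gene, against 0.997 over all genes, and all 4 were called in either replicate's own list. The call for progenitor genes ended with distal peaks more than 5 kb from a TSS (adjusted permutation p = 0.0839), where GABAergic and glycinergic genes had 2.56 per gene. Random lists were not matched on gene length or on the distance to neighbouring genes, which bear on how many peaks a gene is assigned. Nfib (19), Meis2 (14) and Lhx5 (13) held many of the 149 peaks of hindbrain transcription factors. Rbfox3 alone held 24 of the 66 peaks of pan-neuronal genes, and Bcl11b 18 of the 36 peaks of forebrain transcription factors. Lhx5 and some other genes stand in both the hindbrain and the GABAergic list, so these lists share peaks. Forebrain transcription factors had 1.29 and anterior Hox genes 1.67 (adjusted permutation p = 0.133 for both), and no other list passed in the replicated list. In the replicate 1 list forebrain genes had 2.54 (adjusted permutation p = 0.0762), and posterior Hox genes, with 0 distal peaks, were called lower there (adjusted permutation p = 0.0161). The genes with most distal peaks were Gse1 (65), Ncor2 (39), Zmiz1 (34), Ebf3 (28), Rbm19 and Fyn (26 each), Cstad, Zfp423 and Rbfox3 (24 each) and Bach2 (23).

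The distal peak with the highest fold enrichment (32.2) lay between genes on chromosome 8 from 69716231 to 69716958, 6008 bp from the nearest TSS of Zfp869. The next lay between genes on chromosome 12 from 8640743 to 8641741, 33202 bp from Pum2 (30.8), and in an intron of the gene Lncppara on chromosome 15 from 85669699 to 85673352, nearest to Ppara (28.8). The fourth, on chromosome 17 from 88255523 to 88257641 (28.5), lay in an intron and had no protein-coding TSS within 100 kb. The others of the 10, with fold enrichments from 27.2 to 26.3, were nearest to Macf1, Mos, Tnrc18, Gpr161, Sox17 and Foxe1.

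Shared peaks were the stronger ones in both replicates. Of the replicate 2 peaks, 85.0% were overlapped in replicate 1, and of the replicate 1 peaks 48.7% were overlapped in replicate 2, against 1.82% on average for random placements of replicate 1 (one-sided permutation of positions, p = 0.001, the smallest it can give). The bases covered in both made up 56.6% of those covered in either. In the 10% of peaks with the highest fold enrichment, 100% were shared in either direction. In the lowest 10%, 15.3% of replicate 1 peaks and 65.0% of replicate 2 peaks were shared. Peaks at a TSS made up 67.5% of the shared and 20.0% of the unshared replicate 1 peaks. For replicate 2 these shares were 68.0% and 19.2%. Over 28542 matched peaks the fold enrichments of the replicates had a Spearman rho of 0.846 (95% interval 0.842 to 0.849). Peaks within a list are not independent replicates. Among the strongest 20000 peaks of each list, 83.9% of replicate 1 peaks were shared.

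**Figure D4:**
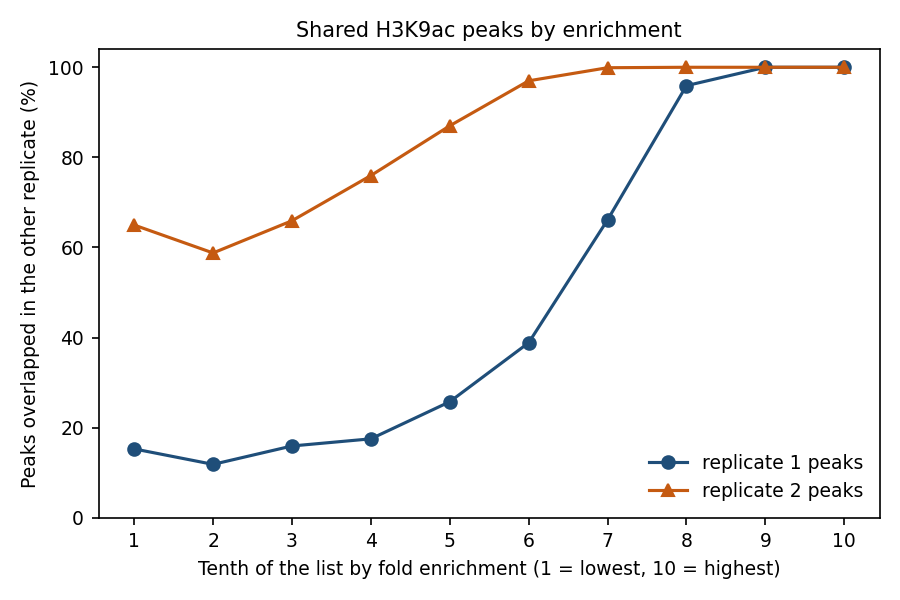
Share of peaks overlapped by at least 1 bp in the other replicate, in percent, for 10 equal bins of fold enrichment within each replicate's own list. Sharing is 15.3% in the lowest bin, 11.9% in the next and 100% in the highest for replicate 1, and 65.0%, 58.8% and 100% for replicate 2.

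The replicated list kept 39443 of the 50764 pooled peaks, 77.7% (Wilson 95% interval 77.3 to 78.1). Kept peaks had a median fold enrichment of 5.28 and a median width of 553 bp, and the 11321 dropped peaks 3.01 and 207 bp (permutation p = 1e-05 for each, the smallest it can give). The replicated list was itself made from the other lists, so this difference may follow from how peaks were kept, and its p is a description only. Of the kept peaks, 68.8% overlapped a peak in both replicate lists, 24.5% in replicate 1 only, 3.77% in replicate 2 only and 2.92% in neither. Among dropped peaks, 59.1% overlapped a replicate 1 peak and 12.2% a replicate 2 peak.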

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

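The replicated list held 9 peaks on unplaced or unlocalised scaffolds, which no comparison by chromosome position or gene used. They were part of the counts of peaks and of the comparison of kept with dropped pooled peaks. No expected number for scaffolds was computed and there are no control samples, so whether 9 is more than chance gives is open.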

How the results depend on the processing

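Tests with TSSs of coding transcripts only, with genes that have no other TSS within 2 kb, with the 5′ end in the CpG comparison, with CpG-matched random lists for lists other than microglia genes, and of Hox coverage by replicate were chosen after seeing the data. Overlap between replicates, the share of peaks at a TSS, the CpG difference, and the Hox difference kept their direction and their side of the threshold under every alternative run for them, and the numbers of lists called for enrichment and for distal peaks stayed within 1.5 times their value. The Hox difference ranged from 73.8 to 93.8 percentage points. The difference between hindbrain and forebrain transcription factors, 21.03 points and not called, was called with a q value of 0.01 or less (28.2), a TSS window of 500 bp (24.6), the 5′ end of the gene (36.1), the pooled list (20.2) and coding transcripts only (24.6), and not with a window of 2 kb (17.5) or among genes with no other TSS within 2 kb (9.24). It lay between 13.9 and 43.3 points when either replicate was left out. The cause was not tested. The share of forebrain genes with a TSS peak, 67.9%, turned from above to below other genes without replicate 1 (42.9%; 75% without replicate 2) and, because nearly all other CpG-rich promoters were marked, among CpG-rich promoters (73.7%). It was also below other genes, without a call, at a q value of 0.01 or less (60.7%), with a window of 500 bp (64.3%), with the 5′ end (50%) and with coding transcripts only (64.3%). Among CpG-rich promoters the hindbrain list also fell below other genes (90.6%), and the liver list, then very small, rose above them (100%). The number of lists called fell from 14 to 4 among CpG-rich promoters, with 0 higher, where fewer genes were tested. Against CpG-matched lists 7 lists were called, 3 of them higher, and the shares of hindbrain (88.9%) and forebrain genes (67.9%), above other genes, were below those of their matched lists. Lists called for domain width went from 14 to 7 without joining peaks. The share of genes with a TSS peak was 61.6% with the 5′ end alone and 56.0% for genes with no other TSS within 2 kb. Spearman's rho was 0.862 with an overlap of 50% of the shorter peak and 0.871 with −log10 p. At a q value of 0.01 or less, 90.01% of pooled peaks were kept. Requiring the replicated list to cover 50% of a pooled peak changes nothing by construction, since each replicated peak is a pooled peak. Overlap and rank results cannot be had without a replicate. No read depth is known, so its effect was not tested.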

Other observations

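The tests of gene families, of the X chromosome, and of forebrain against posterior Hox genes were chosen after results had been seen. Several gene families stood apart from the 65.4% of genes with a TSS peak (12 families, Fisher's exact tests, Benjamini-Hochberg). Olfactory receptor genes had one at 2 of 1135 and vomeronasal receptor genes at 1 of 329 (adjusted exact p = 6.92e-151 for the latter). Beta-defensin genes had one at 0 of 42 (adjusted exact p = 1.20e-19) and keratin genes at 5 of 53 (adjusted exact p = 5.90e-17). Ribosomal protein genes had one at 73 of 76 (adjusted exact p = 3.40e-10), zinc finger protein genes named Zfp at 340 of 394 (adjusted exact p = 1.67e-20), potassium channel genes at 75 of 94 (adjusted exact p = 0.00376) and solute carrier genes at 271 of 371 (adjusted exact p = 0.00224). Replication-dependent histone genes had one at 55 of 67 (adjusted exact p = 0.00434), with 83.6% in replicate 1, but 62.7% in replicate 2, which is below the 64.3% of all genes there. The clustered protocadherins, cell surface proteins of which single neurons use few, were marked less often: alpha genes at 2 of 14 (adjusted exact p = 0.000185), beta genes at 0 of 22 (adjusted exact p = 1.41e-10) and gamma genes at 7 of 21 (adjusted exact p = 0.00434). Gamma genes stood at 52.4% in replicate 1 and 23.8% in replicate 2, beta genes at 4.55% and 0, and keratin genes at 15.1% and 9.43%. Members of a cluster share a neighbourhood and are not independent of each other.

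X-linked genes had a TSS peak less often than autosomal genes, and a lower fold enrichment where one was present. A TSS peak was found at 467 of 948 X-linked genes (49.3%) and at 66.7% of autosomal genes (Fisher's exact test, p = 3.64e-27), although the 19 autosomes themselves ranged from 54.6% to 79.2%. Among CpG-rich promoters the shares were 92.9% and 97.7% (exact p = 3.77e-05). Where a peak was present, the median fold enrichment was 10.8 on the X chromosome and 17.8 on autosomes, a ratio of 1.64, and no autosome lay outside 16.1 to 18.9 (permutation p = 1e-05, the smallest it can give). Within the replicate lists the ratio was 1.57 and 1.68, and among CpG-rich promoters of the replicated list it was 1.73. The pools held embryos of both sexes, and no value was adjusted for the number of X copies. Why the X chromosome stood lower was not tested.

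No microglia or leukocyte gene had a replicated TSS peak. Low CpG content of these promoters, with a median ratio of 0.211, was a candidate explanation. Random lists matched on CpG ratio had a TSS peak at 4.00 genes on average (95% of lists between 1 and 7). A share of 0.0076 of 10000 lists had as few, under the 0.05 set in advance for arguing against CpG content (adjusted permutation p = 0.0456 over 21 lists). The ratio was taken at the 5′ end of the gene, however, and a peak at any TSS counted. With peaks at the 5′ end only, 13.4% in place of 21.9% of genes with a ratio under 0.4 were marked. No matched lists were drawn that way, so CpG content as the whole cause stays open. A signal of a minor cell type too weak to be called may also leave these promoters blank: 3 of the 15 had a TSS peak in at least 1 of the 4 lists, against 3 of 34 liver and germ cell genes (Fisher's exact test, p = 0.353), so an absent and a faint signal cannot be told apart in these lists. The design holds no second group, and no biological explanation was tested.

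TSS peaks at forebrain transcription factors were weak, with a median fold enrichment of 4.46 against 8.60 at hindbrain factors, and 9 of the 28 genes had one in replicate 1 only, against 1 of 36 hindbrain genes; CpG-matched lists held 23.8 marked genes against their 19. Promoters of neighbouring genes do not account for them, since 76.5% of the 17 list genes with no other TSS within 2 kb had one. Faint peaks at any silent CpG-rich developmental promoter were mostly missing at posterior Hox genes, of which 6.25% had one (Fisher's exact test, p = 9.11e-05). This comparison was chosen with both counts known, and Hox genes lie in 4 clusters and may not stand for other silent genes. Heart and skeletal muscle genes were marked at 7 of 19 with a median of 4.43, though at a lower median CpG ratio (0.254 against 0.661 for forebrain genes). Faint peaks at silent promoters outside the Hox clusters therefore stay open. Some forebrain tissue in the samples stays open: of 15 telencephalic and hypothalamic genes set in advance, 2 (Nkx2-1 and Six3) had no TSS peak in any list, within the 4 that this explanation allows. Low acetylation of these genes in hindbrain cells would give the same values and was not tested.

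Replicate 1 had 1.44 times as many peaks as replicate 2. Domains broken into more peaks are argued against, since after joining peaks within 1 kb the ratio was 1.51. Weak peaks near the calling threshold may account for part of the surplus: 80.7% of replicate 1 peaks without a partner lay in the lower 50% of its enrichment values, between the 75% and 90% set in advance, so this cannot be told apart from other causes. The ratio was 1.43 among peaks with a q value of 0.01 or less, a limit that kept 80.6% of replicate 1 and 81.4% of replicate 2 peaks. Such similar shares leave the ratio nearly unchanged, so this value cannot decide the question. Many weak replicate 1 peaks without a partner also passed the limit. Among peaks that passed, 13.6% were shared in the lowest enrichment bin of replicate 1, and 71.1% in that of replicate 2. Read depth and the control used for each replicate are unknown here, and no biological explanation was tested.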
